A study of Mus musculus with 24 samples.

How the data were processed

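The series measured gene expression in whole liver of wild-type C57BL/6 mice that ate 1 of 6 diets for 8 weeks from an age of 8 to 10 weeks. Per the labels' protocols, total RNA was made into strand-specific Illumina TruSeq libraries and sequenced from 1 end with 50 bp reads. The diets were normal chow (NC), high sucrose (HS), high sucrose with 2% cholesterol (HS_Chol), high sucrose with cholesterol and cholic acid, 2% cholesterol with cholic acid (Chol_CA) and cholic acid alone (CA). The labels do not say that the libraries are separate animals beyond numbering them, so every p-value here measures the spread between these samples.

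The authors deposited 1 table of raw read counts with 34436 gene symbols, and per the submitters' processing notes the reads had been aligned to mm10 with STAR 2.6.1c, which also counted reads per gene. Neither the notes nor the labels say which strand was counted or how symbols with several gene models were joined. The table had 23 columns of values for 24 labelled samples. Its columns carry a diet name and a number that starts at 0, while the labels number from 1, so 20 columns were matched to a diet but not to a single labelled sample. The library numbers in the text are those of the table. The other 3 columns matched no label and were not used, which left no library for the diet of high sucrose with cholesterol and cholic acid. HS_Chol had 3 columns for its 4 labelled samples. One HS sample carries a diet label of normal chow; it could not be matched to a column, so all 5 HS columns were used and each was left out in turn.

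Symbols were looked up in the GENCODE M21 annotation (GRCm38, the assembly also called mm10), which may not be the annotation used for counting. Of the symbols, 29015 were found as gene names, 1848 through an older name and 3573 not at all; the last held 0.436% of the reads. Dates stood in place of 25 symbols (0.0865% of the reads), and 210 differed from another only in case. No read fell in 12697 rows. Coordinates are 1-based and refer to GRCm38.

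Total reads per library ran from 6110484 to 10244277, with a median of 7639777. Read counts were scaled by effective library size to CPM, the deposited reads of a gene per 1000000 reads. At these depths 3 reads over a group of libraries correspond to between 0.0821 CPM (CA) and 0.158 CPM (HS_Chol). The floor of the group was used where all its libraries had no reads. Intervals for counts and these floors cover counting error only.

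Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr on the diet groups (12595 genes kept), robust dispersion estimates, and robust quasi-likelihood fits with 1 mean per diet over all 20 libraries. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.235. The comparisons were each diet against NC, HS_Chol against HS, Chol_CA against CA, and the difference between the last pair of contrasts, called the cholesterol interaction. The planned comparisons with the sixth diet and the sucrose and cholic acid interactions could not be run without its libraries. Errors beside log2 fold changes are standard errors taken from the fit, and errors beside CPM are standard deviations between libraries.

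Before the data were examined, 45 gene lists were fixed for pathways, nuclear receptor targets, liver cell types and contaminating tissues; 935 of their 941 entries were in the table. Each list was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. List members were counted as called over all genes tested and again adjusted over the list alone. Named genes also followed a rule fixed before the data were examined. It took the 4 largest rises and 4 largest falls per comparison among called genes of at least 5 CPM whose groups did not overlap, without predicted models and pseudogenes. It added the 2 members with the smallest adjusted p of the 5 lists that passed with the smallest p, and 12 genes in every comparison, among them Cyp7a1, Cyp8b1, Sqle, Abcg5 and Trem2. For the interaction it took the 3 largest differences of each sign, without the condition on overlap. A few genes were added outside the rule, and the text says so where they appear.

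The whole procedure was first tested on simulated counts. They were made from each gene's mean over the 5 diets and its fitted dispersion, at the sizes of all 20 libraries. For each comparison a separate list of genes was raised 2-fold for the list test, and 100 genes were changed 2-fold and 100 changed 4-fold. The tests recovered 62% and 86% of them for HS against NC, 50% and 84% for HS_Chol against NC, 54% and 90% for Chol_CA against NC, and 59% and 92% for CA against NC. The shares were 45% and 87% for HS_Chol against HS and 51% and 88% for Chol_CA against CA. Between 5 and 10 unchanged genes were called per simulation. The simulated counts held no trend with transcript length and no reads on the wrong strand, so these shares need not hold in the data.

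Calls shared by 2 diets against the same NC libraries were set beside the number that independent lists would share, 20 simulations of unchanged groups, and a split of the NC libraries in which each diet was compared with other controls. Alternatives planned before the data were examined were median-ratio size factors, no filter and a stricter filter on low counts (2 CPM in 3 libraries), leaving out mitochondrial, rRNA and small RNA genes, fitting only the groups compared, DESeq2 1.42.0, a 2-fold minimum change, and leaving out each library. Chosen after seeing the data were leaving out genes that overlap a gene on the opposite strand or match no annotated gene, a term for the sign of a library's trend with transcript length, leaving out the 7 libraries with a negative trend, and an offset for transcript length and GC content. Where leaving out a library left few in a group, the fit pooled the spread over all diets. Other splits of the libraries of each comparison were counted, all of them where there were at most 100 and 100 drawn at random otherwise.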

Results

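Expression of all genes was measured by RNA sequencing in livers of mice on 5 of the 6 diets: 4 NC libraries, 5 HS, 3 HS_Chol, 4 Chol_CA and 4 CA. Total reads per library ran from 7598660 to 8215500 in NC, 6790751 to 7769883 in HS, 6110484 to 6709497 in HS_Chol, 6750266 to 8886641 in Chol_CA and 7850495 to 10244277 in CA. Sucrose feeds fat synthesis in the liver, cholesterol loads it with sterol, and cholic acid is a bile acid that aids cholesterol uptake and acts on bile acid receptors.

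Measures of the libraries themselves differed between and within diets. Reads on light-strand tRNA genes of mitochondrial DNA, a measure that reads assigned to the wrong strand would raise, stood at 673 to 900 per 1000000 heavy-strand mRNA reads in the 3 HS_Chol libraries and at 8.95 to 83.4 in the other 17. The trend of read counts with transcript length was negative in 7 libraries (NC_3, HS_0, HS_1, HS_2, CA_0, Chol_CA_0 and Chol_CA_1) and positive in the other 13.

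**Figure D1:**
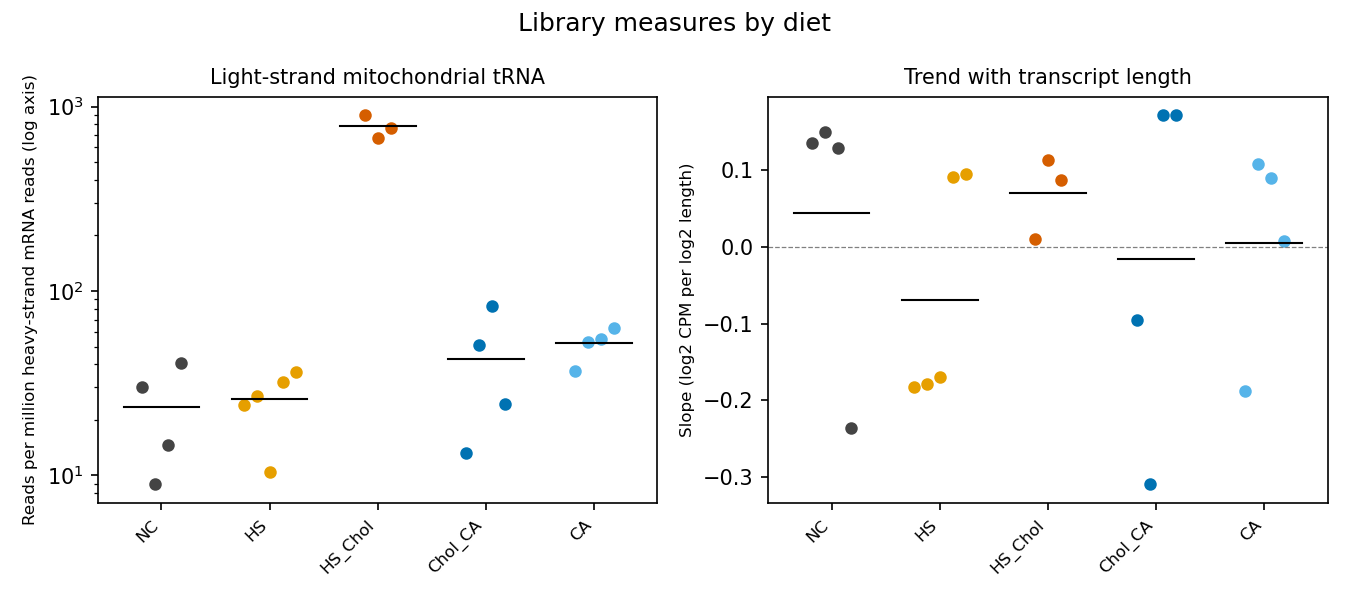
Left, reads on light-strand mitochondrial tRNA genes per 1000000 heavy-strand mRNA reads on a log axis; right, slope of log2 CPM, relative to the gene's mean over libraries, on log2 transcript length. Each point is a library and each bar the mean of its diet; the 3 HS_Chol libraries lie at 673 to 900 in the left panel, and 7 libraries lie below 0 in the right panel.

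High sucrose against chow asks what the HS diet as a whole changed. Sucrose was not separated from any other difference between the feeds. Pnpla3, which encodes a lipid-droplet lipase (chromosome 15, 84167837 to 84187236), rose from 3.26 ± 3.13 CPM (SD, n = 4) in NC to 27.4 ± 12.3 CPM (n = 5), a log2 fold change of 3.07 ± 0.45 (SE; adjusted p = 0.00128). Apoa4, an apolipoprotein of triglyceride-rich particles (chromosome 9, 46240696 to 46243459, overlapped on the other strand by a weakly read gene), rose from 181 ± 44.1 to 1030 ± 395 CPM (log2 fold change 2.51 ± 0.35, adjusted p = 0.000828). The zinc importer gene Slc39a4 fell from 91.3 ± 17.6 to 12.2 ± 4.51 CPM (log2 fold change −2.90 ± 0.26, adjusted p = 7.02e-06), and the drug-metabolizing Cyp3a11 from 3615 ± 560 to 516 ± 212 CPM (log2 fold change −2.81 ± 0.27, adjusted p = 8.32e-06).

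Of 23 measured genes of fatty acid synthesis under SREBP1c and ChREBP, 3 rose and none fell, or 5 adjusted over the list alone (camera adjusted p = 8.59e-09, adjusted p = 0.314 with an estimated correlation). Pnpla5, next to Pnpla3 on the chromosome, was among them with a log2 fold change of 3.58 ± 0.52, while Fasn (0.29 ± 0.41) and Scd1 (0.33 ± 0.32) did not pass. Of 22 drug-metabolism genes under the receptors CAR and PXR, 6 fell, or 13 adjusted over the list alone, where 1 rose (camera adjusted p = 2.36e-20, adjusted p = 0.103 with an estimated correlation). Abcc3, an export pump for conjugates, fell by 2.10 on the log2 scale. The PPARalpha target Cyp4a14, whose reads Cyp4a10 may share, fell from 640 ± 363 to 45.8 ± 42.3 CPM (−3.80 ± 0.61, adjusted p = 0.00303). Of 23 NRF2 and glutathione genes 6 fell, or 8 adjusted over the list alone, where 1 rose (camera adjusted p = 2.14e-11, adjusted p = 0.214 with an estimated correlation). Ephx1 fell by 1.60 and Gclc by 0.94. Of 17 immediate early genes Egr1 (log2 fold change −2.66 ± 0.43) and Fos (−2.19 ± 0.47) fell, or 5 adjusted over the list alone (camera adjusted p = 6.04e-06, adjusted p = 0.166 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 53.8 ± 17.5 CPM in NC and 18.3 ± 10.7 in HS (log2 fold change −1.55 ± 0.36, adjusted p = 0.0514). It passed without HS_3 (adjusted p = 0.00716), with DESeq2 (0.00746), with an offset for length and GC content (0.0277) and with a stricter filter (0.0467). That was 1 of 9 fits without a library, and in the remaining alternatives it did not pass either. No interferon-stimulated gene of 26 passed over all genes by edgeR, 2 were higher adjusted over the list alone, and the list as a whole leaned upward (camera adjusted p = 4.07e-08, adjusted p = 0.413 with an estimated correlation).

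Over 12595 genes tested with edgeR's quasi-likelihood test, 27 were higher and 55 lower in HS. Without 1 library the higher genes numbered 12 (NC_0), 12 (NC_1), 6 (NC_2), 58 (NC_3), 17 (HS_0), 13 (HS_1), 17 (HS_2), 10 (HS_3) or 13 (HS_4), and the lower genes 29 (NC_2), 100 (NC_3), 35 (HS_1), 34 (HS_3) or 31 (HS_4). Among libraries with a positive length trend (3 NC, 2 HS) 148 genes were higher and 183 lower; Apoa4 (log2 fold change 2.37, adjusted p = 0.0654), Cyp4a14 (−3.87, 0.0751), Egr1 (−2.11, 0.101) and Fos (−2.03, 0.0739) did not pass with these fewer libraries. Fos also lost its call without any 1 of NC_1, NC_2 and the 5 HS libraries (adjusted p 0.0648 to 0.136).

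Cholesterol with sucrose, against chow, lowered the genes of cholesterol synthesis. Sqle, which encodes squalene epoxidase (chromosome 15, 59315077 to 59331192), fell from 67.7 ± 5.97 CPM (n = 4) to 2.70 ± 0.39 CPM (n = 3), a log2 fold change of −4.64 ± 0.43 (adjusted p = 1.41e-06). Sc4mol, the sterol C4 methyl oxidase gene now named Msmo1, fell from 152 ± 48.8 to 27.0 ± 8.48 CPM (log2 fold change −2.49 ± 0.23, adjusted p = 1.47e-06). Abcg5 and Abcg8, the subunits of the canalicular sterol exporter, rose by 2.06 ± 0.20 (adjusted p = 2.17e-06) and 1.81 ± 0.21 (adjusted p = 1.92e-05) on the log2 scale, with reads that their overlap on opposite strands leaves partly uncertain. Cyp7a1 stood at 64.3 ± 12.2 CPM (log2 fold change 0.26 ± 0.40, adjusted p = 0.912).

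Of 24 measured genes of cholesterol synthesis and other SREBP2 targets, 16 fell and none rose, or 23 adjusted over the list alone (camera adjusted p = 5.26e-61, adjusted p = 0.00052 with an estimated correlation). Of 14 LXR target genes 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 3.68e-11, adjusted p = 0.00052 with an estimated correlation). Of 18 periportal hepatocyte genes 2 fell, or 4 adjusted over the list alone (camera adjusted p = 0.000221, adjusted p = 0.0291 with an estimated correlation). Of 13 Kupffer cell markers 4 rose, or 11 adjusted over the list alone (camera adjusted p = 2.14e-12, adjusted p = 0.219 with an estimated correlation). Cd5l, a secreted macrophage protein, stood at 23.6 ± 2.57 CPM in NC and 109 ± 65.8 in HS_Chol (adjusted p = 0.00466), and without HS_Chol_0 it did not pass (adjusted p = 0.0725). Of 15 dendritic cell and MHC class II genes Cd74 (log2 fold change 2.36 ± 0.59) and Ciita (2.13 ± 0.55) rose, or 10 adjusted over the list alone (camera adjusted p = 2.10e-06, adjusted p = 0.271 with an estimated correlation). Cd74 lost its call without NC_0, NC_1, NC_2, HS_Chol_0 or HS_Chol_1 (adjusted p 0.0687 to 0.402), without a filter (0.0965), in a fit of these 2 diets alone (0.0539) and without opposite-strand genes (0.0802). Ciita lost its call without HS_Chol_0 or any 1 NC library (0.0553 to 0.667), with a stricter filter (0.0521) and with the length and GC offset (0.078). Without HS_Chol_0 the log2 fold changes went to 1.599 for Cd74 and 1.035 for Ciita. Without any other of these libraries both stayed at 1.881 or more.

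In HS_Chol 216 genes were higher and 71 lower than in NC by edgeR, and without HS_Chol_0 only 36 were lower. Of the 216, 134 overlap a gene on the opposite strand or match no annotated gene, as did 2324 of the 12595 tested. The largest rises were such genes: Dlec1, which overlaps the end of the abundant Acaa1b, stood at 23.9 ± 4.48 CPM against 0.98 ± 1.05, and the light-strand mt-Tp at 40.6 ± 4.01 CPM against 1.30 ± 1.41. With such genes left out 48 were higher and 41 lower, and among libraries with a positive length trend (3 NC, 3 HS_Chol) 796 were higher and 620 lower.

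Cholic acid alone, against chow, lowered bile acid synthesis and raised drug-metabolizing genes. Cyp8b1, the enzyme that makes cholic acid (chromosome 9, 121914356 to 121916305), fell from 621 ± 151 CPM (n = 4) to 1.40 ± 0.60 CPM (n = 4), a log2 fold change of −8.76 ± 0.36 (adjusted p = 6.26e-12). Cyp7a1 fell from 53.8 ± 17.5 to 0.49 ± 0.60 CPM (log2 fold change −6.67 ± 0.56, adjusted p = 3.32e-07). Cyp2b9, a steroid hydroxylase that female livers express more (chromosome 7, 26173411 to 26210661; its reads may be shared with its near-identical neighbour Cyp2b13), rose from 0.52 ± 0.41 to 167 ± 118 CPM (log2 fold change 8.29 ± 0.69, adjusted p = 3.28e-07). The bile acid exporter subunit gene Ostb, now named Slc51b, rose by 5.18 ± 0.41 on the log2 scale, while Nr0b2, the nuclear receptor SHP, stood at 80.3 ± 9.32 and 100 ± 19 CPM (adjusted p = 0.522).

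Of 16 bile acid synthesis genes 8 fell and none rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 1.68e-15, adjusted p = 0.000603 with an estimated correlation). Of 22 CAR and PXR targets 17 rose and 1 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 3.98e-22, adjusted p = 0.0277 with an estimated correlation). Of 25 male-biased liver genes 18 fell, or 22 adjusted over the list alone (camera adjusted p = 3.87e-33, adjusted p = 0.0269 with an estimated correlation). Susd4 fell by 6.94 ± 0.56 on the log2 scale. Mup7 (log2 fold change −7.43 ± 0.89) and Mup11 (−7.30 ± 0.90), whose reads near-identical paralogs may share, fell too. Of 14 female-biased genes 11 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 1.97e-11, adjusted p = 0.056 with an estimated correlation). The 4 CA libraries held Cyp2b9 at 24.6 (CA_0), 121, 291 and 232 CPM. Of 24 cholesterol synthesis genes 22 fell, or 24 adjusted over the list alone (camera adjusted p = 1.84e-45, adjusted p = 0.00164 with an estimated correlation), with Sqle at −4.05 ± 0.35. Of 18 pericentral hepatocyte genes 12 fell, the same adjusted over the list alone (camera adjusted p = 3.98e-24, adjusted p = 0.00016 with an estimated correlation). Among them were the glutamine synthetase gene Glul (log2 fold change −1.92 ± 0.16), which a gene on the other strand overlaps, and the glutamate transporter gene Slc1a2 (−2.31 ± 0.20). All 13 Kupffer cell markers rose, by both counts adjusted over all genes and adjusted over the list alone (camera adjusted p = 9.09e-16, adjusted p = 0.0576 with an estimated correlation). Cd5l rose from 23.6 ± 2.57 to 133 ± 44.1 CPM.

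In CA 657 genes were higher and 581 lower by edgeR. The higher genes numbered 376 without NC_0, 422 without NC_2 and 423 without CA_3. Among libraries with a positive length trend (3 NC, 3 CA) 1423 were higher and 1385 lower, and with a term for the sign of the trend 1036 and 968.

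Cholesterol with cholic acid, against chow, changed the most genes. Gpnmb, a marker of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), rose from 0.21 ± 0.25 CPM (n = 4) to 127 ± 54.0 CPM (n = 4), a log2 fold change of 9.15 ± 0.59 (adjusted p = 5.51e-09). Trem2, a lipid receptor of macrophages, rose from 0.17 ± 0.18 to 12.1 ± 7.41 CPM (log2 fold change 5.99 ± 0.69, adjusted p = 3.44e-06), and the collagen gene Col1a1 from 12.6 ± 3.46 to 108 ± 76.5 CPM (3.11 ± 0.54, adjusted p = 0.00022). Cyp8b1 fell from 621 ± 151 to 7.85 ± 3.48 CPM (−6.31 ± 0.32, adjusted p = 2.04e-10). Cyp4a14 fell from 640 ± 363 to 2.39 ± 1.59 CPM (−8.09 ± 0.85, adjusted p = 1.49e-06), and Sqle from 67.7 ± 5.97 to 1.37 ± 0.49 CPM (−5.59 ± 0.40, adjusted p = 2.19e-08).

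Of 24 cholesterol synthesis genes all 24 fell, also adjusted over the list alone (camera adjusted p = 1.19e-47, adjusted p = 0.00302 with an estimated correlation). Of 32 fatty acid oxidation genes and PPARalpha targets 29 fell, or 31 adjusted over the list alone (camera adjusted p = 5.27e-31, adjusted p = 0.0048 with an estimated correlation). Eci2, an enoyl-CoA isomerase gene, fell by 1.23 ± 0.13. Of 20 markers of monocyte-derived and lipid-associated macrophages 19 rose, the same adjusted over the list alone (camera adjusted p = 4.00e-22, adjusted p = 0.0308 with an estimated correlation). Of 27 chemokine and inflammatory genes 25 rose, the same adjusted over the list alone (camera adjusted p = 6.81e-19, adjusted p = 0.0631 with an estimated correlation), such as the adhesion molecule gene Vcam1 (3.73 ± 0.37). Of 13 Kupffer cell markers 12 rose, the same adjusted over the list alone (camera adjusted p = 5.91e-15, adjusted p = 0.0613 with an estimated correlation). Of 35 extracellular matrix and fibrosis genes 27 rose, or 28 adjusted over the list alone (camera adjusted p = 1.44e-10, adjusted p = 0.154 with an estimated correlation). With diet in the fit, 18 of these 35 genes and 13 of the 20 macrophage markers were also higher in the 7 libraries with a negative length trend, which include 2 of Chol_CA and 1 of NC (camera adjusted p = 0.0131 and 0.0245, adjusted p = 0.903 for both with an estimated correlation). Of the 27 chemokine and inflammatory genes 11 were higher there and 0 lower (camera adjusted p = 0.0718, adjusted p = 0.903 with an estimated correlation). Among libraries with a positive trend 23 matrix genes and 19 macrophage markers were higher in Chol_CA and 1 matrix gene lower. Of 23 fatty acid synthesis genes 16 fell, or 17 adjusted over the list alone (camera adjusted p = 5.33e-13, adjusted p = 0.0613 with an estimated correlation). Slc2a6, a hexose transporter gene, had no reads in NC and 7.39 ± 7.37 CPM in Chol_CA, at least 71.3-fold higher than the floor of 3 reads over the NC libraries. Clec4e, a receptor of myeloid cells, had 1 read in NC and 885 in Chol_CA, a ratio of 895 with a 95% exact counting interval of 160 to 35400. Its reads numbered 275 and 534 in Chol_CA_0 and Chol_CA_1, which have a negative length trend, and 48 and 28 in the others. The 2 Chol_CA libraries with a negative length trend held Col1a1 at 159 and 188 CPM and the others at 49.0 and 36.9 CPM.

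Of the genes tested, 1885 were higher and 1178 lower by edgeR; a minimum change of 2-fold left 360 lower, and a fit of these 2 diets alone gave 701 lower. Cyp7a1 was lower (22.8 ± 8.04 CPM; log2 fold change −1.24 ± 0.38; adjusted p = 0.0201) but did not pass with fewer libraries: without NC_0, NC_3 or Chol_CA_2 (log2 fold changes −1.12, −1.05 and −0.997, adjusted p 0.0576 to 0.0715) or among libraries with a positive length trend (−1.21, 0.117).

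**Figure D2:**
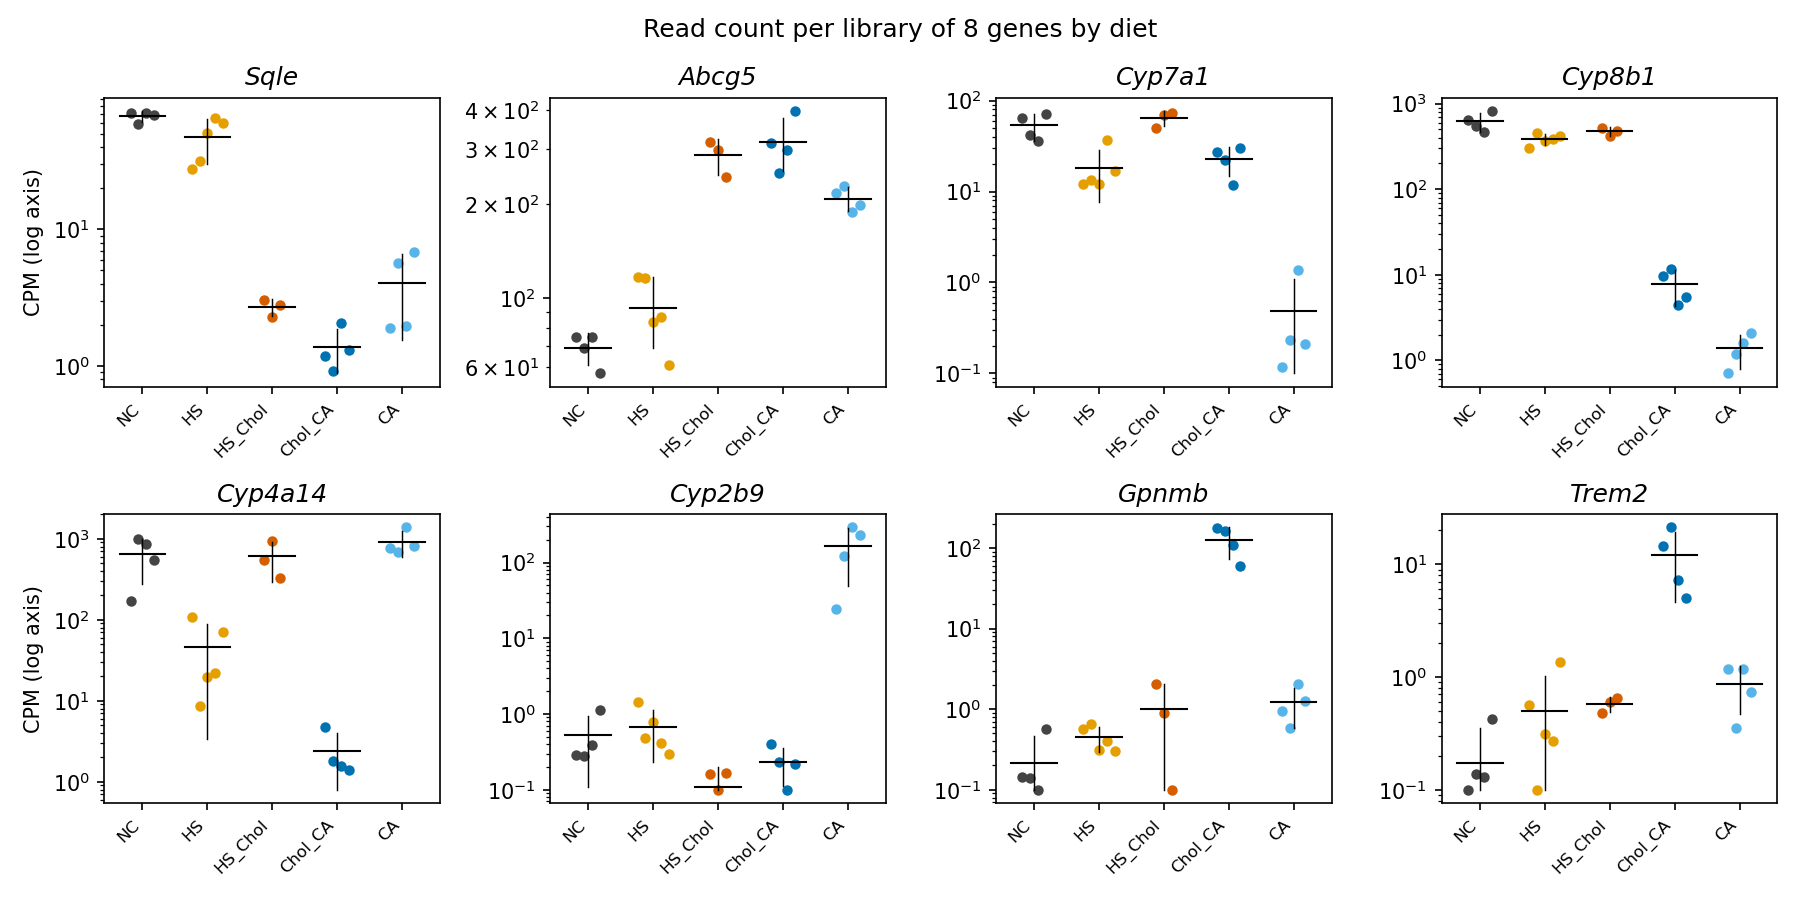
CPM of 8 genes in each library on log axes, by diet; bars are means and lines 1 SD, and values under 0.1 CPM are drawn at 0.1. Sqle lies at means of 67.7 CPM in NC and 2.70 to 1.37 CPM in HS_Chol and Chol_CA, Cyp7a1 at 0.49 CPM in CA, and Gpnmb at 127 CPM in Chol_CA.

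Cholesterol added to sucrose, HS_Chol against HS, compares the diets with and without the sterol. It does not isolate the sterol, since the libraries differed as well. Light-strand tRNA reads per 1000000 heavy-strand mRNA reads stood at 673 to 900 in HS_Chol and at most at 83.4 in all other libraries. The length trend was negative in 3 of the HS libraries and 0 of the HS_Chol libraries. Sqle fell from 47.2 ± 16.9 CPM (n = 5) to 2.70 ± 0.39 CPM (n = 3), a log2 fold change of −4.13 ± 0.42 (adjusted p = 2.98e-06), and Nsdhl, another enzyme gene of cholesterol synthesis, fell by 2.10 ± 0.26 (adjusted p = 2.54e-05). Lpl, which encodes lipoprotein lipase, rose from 32.7 ± 4.97 to 128 ± 13.0 CPM (log2 fold change 1.96 ± 0.22, adjusted p = 9.58e-06). Abcg5, overlapped by Abcg8, rose by 1.63 ± 0.18 (adjusted p = 9.58e-06). Cyp17a1, a steroid hydroxylase gene, fell by 3.49 ± 0.40 (adjusted p = 1.04e-05). Cyp7a1 rose from 18.3 ± 10.7 to 64.3 ± 12.2 CPM (1.81 ± 0.38, adjusted p = 0.00955), a call lost without HS_Chol_1 (1.73, 0.0557) and among libraries with a positive length trend (1.25, 0.233).

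Of 24 cholesterol synthesis genes 15 fell, or 19 adjusted over the list alone (camera adjusted p = 6.54e-39, adjusted p = 0.00494 with an estimated correlation). Of 14 LXR targets 4 rose and none fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 5.95e-07, adjusted p = 0.00494 with an estimated correlation). Of 23 fatty acid synthesis genes 6 fell, or 13 adjusted over the list alone, where 1 rose (camera adjusted p = 7.23e-09, adjusted p = 0.355 with an estimated correlation). Acss2, which a gene on the other strand overlaps, fell by 1.58 ± 0.25. Of 22 CAR and PXR targets 5 rose, or 6 adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.467 with an estimated correlation), such as Abcc3 (2.51 ± 0.30) and Cyp3a11 (1.99 ± 0.28). Cfd, which encodes the adipocyte protease adipsin, had 2 reads in HS and 1190 in HS_Chol, a ratio of 1110 with a 95% exact counting interval of 306 to 9160. It stood at 110, 73.0 and 2.79 CPM in the 3 HS_Chol libraries and did not pass among the fewer libraries with a positive length trend (2 HS, 3 HS_Chol; fitted log2 fold change 9.48 against 9.68, no bound, adjusted p = 0.156). Of 4 measured adipose genes Cfd alone was called, also adjusted over the list alone (camera adjusted p = 0.446). Ostb had no reads in HS_Chol and 27 in HS, at least 5.17-fold lower than HS by the floor of 3 reads over the group, with a call (adjusted p = 0.0136) lost without HS_Chol_0 or HS_Chol_1 (0.0637 and 0.0593) and among libraries with a positive length trend (0.198).

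By edgeR 201 genes were higher and 82 lower; 132 of the 201 overlap a gene on the opposite strand or match no annotated gene, and 45 higher and 45 lower remained with such genes left out. The lower genes numbered 53 without HS_1, 33 without HS_Chol_0, 38 without HS_Chol_1, 49 without HS_Chol_2, and 180 among libraries with a positive length trend (2 HS, 3 HS_Chol).

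Cholesterol added to cholic acid, Chol_CA against CA, compares the diets with and without the sterol beside the bile acid. Gpnmb rose from 1.22 ± 0.63 CPM (n = 4) to 127 ± 54.0 CPM (n = 4), a log2 fold change of 6.66 ± 0.47 (adjusted p = 4.80e-08). Cyp2b9 fell from 167 ± 118 to 0.24 ± 0.12 CPM (−9.44 ± 0.74, adjusted p = 1.53e-07) and Cyp4a14 from 908 ± 317 to 2.39 ± 1.59 CPM (−8.60 ± 0.86, adjusted p = 3.02e-06), with reads that paralogs may share. Cyp7a1 rose from 0.49 ± 0.60 to 22.8 ± 8.04 CPM (5.43 ± 0.56, adjusted p = 4.21e-06) and Cyp8b1 from 1.40 ± 0.60 to 7.85 ± 3.48 CPM (2.45 ± 0.33, adjusted p = 5.47e-05). Ces2a, a carboxylesterase gene, fell from 1337 ± 562 to 119 ± 6.22 CPM (−3.49 ± 0.24, adjusted p = 4.80e-08).

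Of 32 fatty acid oxidation genes 29 fell, or 30 adjusted over the list alone (camera adjusted p = 3.79e-39, adjusted p = 0.00359 with an estimated correlation). Ehhadh, a peroxisomal oxidation enzyme gene, fell by 2.17 ± 0.20. Of 22 CAR and PXR targets 18 fell, or 20 adjusted over the list alone, where 1 rose (camera adjusted p = 1.21e-27, adjusted p = 0.021 with an estimated correlation). Of 14 female-biased genes 13 fell, the same adjusted over the list alone (camera adjusted p = 3.40e-18, adjusted p = 0.021 with an estimated correlation), and of 25 male-biased genes 16 rose, or 17 adjusted over the list alone (camera adjusted p = 1.80e-11, adjusted p = 0.181 with an estimated correlation). Of 35 extracellular matrix and fibrosis genes 29 rose, or 31 adjusted over the list alone (camera adjusted p = 2.19e-19, adjusted p = 0.105 with an estimated correlation), such as Col6a3 (1.96 ± 0.23) and Fbn1 (1.64 ± 0.23). Of 20 macrophage markers 18 rose, or 20 adjusted over the list alone (camera adjusted p = 1.85e-17, adjusted p = 0.105 with an estimated correlation). Mmp12, a macrophage elastase gene, rose by 3.86 ± 0.46. With diet in the fit, 18 of the 35 matrix genes and 13 of the 20 macrophage markers were also higher in the 7 libraries with a negative length trend, which include 2 of Chol_CA and 1 of CA (camera adjusted p = 0.0131 and 0.0245, adjusted p = 0.903 for both with an estimated correlation). Among libraries with a positive trend 28 and 16 were higher in Chol_CA. Of 14 LXR targets 6 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.0413 with an estimated correlation). H2-M2, an MHC class I gene, had 1 read in CA and 415 in Chol_CA, a ratio of 478 with a 95% exact counting interval of 85.3 to 18900. Cyp2b10, the classical CAR target, had 3 reads in Chol_CA and 6183 in CA, a ratio of 1790 with an interval of 612 to 8680.

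By edgeR 1693 genes were higher and 983 lower. The higher genes numbered 960 without CA_2 and 1095 without CA_3, and the lower genes 1681 among libraries with a positive length trend (3 CA, 2 Chol_CA) and 1529 with a term for its sign.

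**Figure D3:**
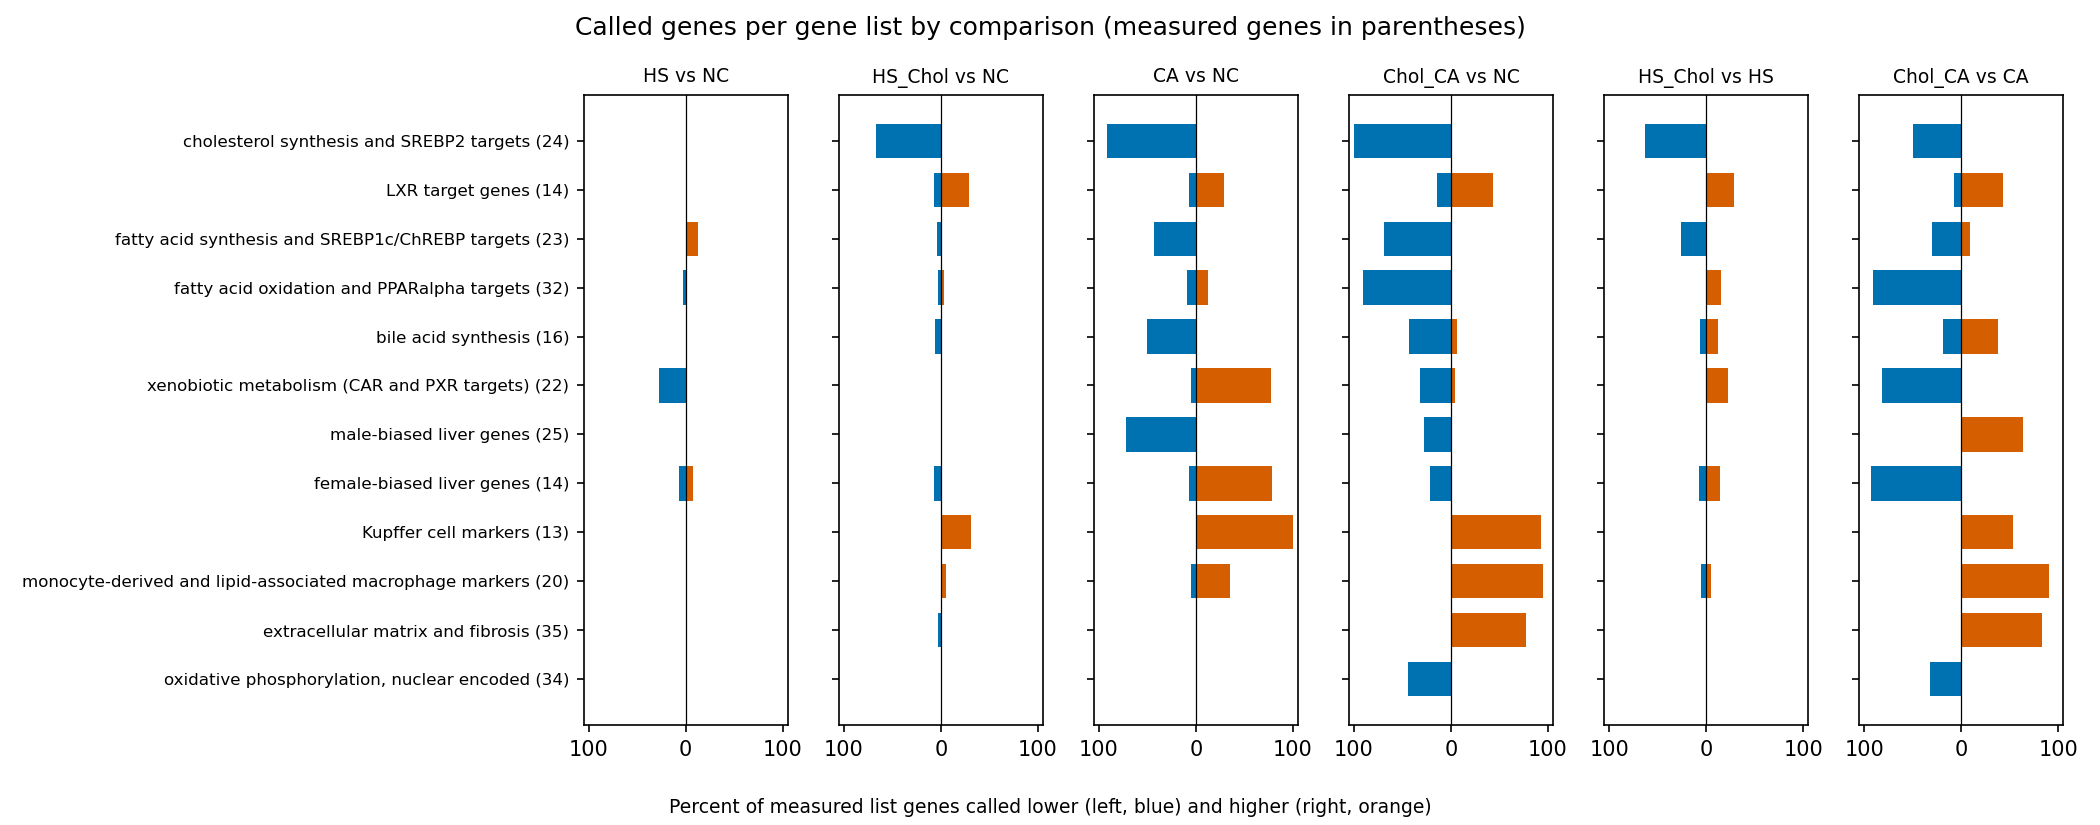
Percent of the measured genes of 12 lists called higher (right) and lower (left) in each comparison, on axes from 0 to 100 each way. All 24 cholesterol synthesis genes lie to the left in Chol_CA vs NC, and all 13 Kupffer cell markers to the right in CA vs NC.

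The cholesterol interaction asks whether cholesterol acted differently beside sucrose than beside cholic acid. Cyp4a14 rose by 3.72 on the log2 scale beside sucrose and fell by 8.60 beside cholic acid, a difference of 12.32 ± 1.06 (adjusted p = 4.55e-07), and Cyp4a10, which may share its reads, differed by 8.01 ± 0.68 (adjusted p = 3.97e-07). Cyp7a1 rose in both backgrounds, by 1.81 and 5.43, and its difference of −3.62 ± 0.71 passed (adjusted p = 0.00357). Sqle fell in both, beside cholic acid with a call lost without CA_3 (adjusted p = 0.0583) and in a fit of CA and Chol_CA alone (0.0663), and its difference was −2.58 ± 0.60 (adjusted p = 0.0139). Without cholesterol, Cyp7a1 and Sqle already stood far lower in CA than in HS. Their differences therefore also depend on unlike starting levels. Trem2 rose by 3.76 beside cholic acid and stood at 0.19 beside sucrose, a difference of −3.57 ± 0.99 (adjusted p = 0.0371).

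Of 32 fatty acid oxidation genes 24 had a positive difference, or 27 adjusted over the list alone (camera adjusted p = 1.24e-45, adjusted p = 0.00144 with an estimated correlation). Of 22 CAR and PXR targets 13 did, or 17 adjusted over the list alone (camera adjusted p = 4.07e-33, adjusted p = 0.00984 with an estimated correlation). Of 25 male-biased genes 12 had a negative difference, or 18 adjusted over the list alone (camera adjusted p = 3.92e-14, adjusted p = 0.27 with an estimated correlation). Of 35 extracellular matrix and fibrosis genes 8 did, or 21 adjusted over the list alone (camera adjusted p = 9.03e-10, adjusted p = 0.32 with an estimated correlation). By edgeR 445 genes had a positive and 311 a negative difference; 149 of the 445 overlap a gene on the opposite strand or match no annotated gene, and a fit without such genes gave 303 and 224. Without CA_0 there were 707 and 608, and the negative ones numbered 130 without CA_2, 156 without CA_3, 191 without HS_Chol_0, 136 without HS_Chol_1, 204 without HS_Chol_2 and 187 without Chol_CA_0. Among libraries with a positive length trend there were 969 and 641.

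Calls against the same NC libraries were compared between diets. With split controls each diet was compared with only a part of the NC libraries, so lower numbers there can also come from fewer controls. The number that independent lists would share was not computed for the split. Chol_CA and CA shared 405 higher and 308 lower genes, where independent lists would share 98.3 and 54.3; with each diet compared with other NC libraries they shared 80 and 169, or 151 and 142 with the NC libraries exchanged. HS_Chol and Chol_CA shared 83 higher and 56 lower (32.3 and 6.6 if independent), and 22 and 28, or 14 and 34, with split controls. HS_Chol and CA shared 69 and 43 (11.3 and 3.3 if independent), and 8 and 25, or 10 and 22, with split controls. HS and HS_Chol shared 4 and 8 (0.5 and 0.3 if independent), and 0 and 3 with either split of the controls. HS and Chol_CA shared 8 and 29 (4 and 5.1 if independent), and 0 and 12, or 1 and 13, with split controls. HS and CA shared 1 and 7 (1.4 and 2.5 if independent), and 0 and 4, or 0 and 5, with split controls, and 23 genes were called in opposite directions. In 20 simulations of unchanged groups against the same controls no gene was shared, and the covariance of log2 fold changes was 0.045, against 0.528 for Chol_CA with CA (0.512 and 0.555 with split controls) and 0.078 for HS with CA (0.042 and 0.005 with split controls). Their Pearson r was above the simulated one for Chol_CA with CA (0.63 against 0.515) and HS_Chol with Chol_CA (0.529 against 0.46). It was below for HS with HS_Chol (0.42 against 0.479), HS with Chol_CA (0.404 against 0.531) and HS with CA (0.223 against 0.534). HS_Chol with CA was also below (0.387 against 0.462). The simulated groups held no length-trend sets, so 0.045 may be too low for these data. Of the genes that cholesterol changed beside sucrose and beside cholic acid, 20 were higher in both, 27 lower in both and 48 opposite, where independent lists would share 27 higher and 6.4 lower (Pearson r of log2 fold changes 0.131). Without genes that overlap a gene on the opposite strand or match no annotated gene, the numbers were 17, 20 and 34, against 10 and 5.2 (Pearson r 0.237).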

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

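The tests that weigh the strand, length-trend and sex-biased patterns were chosen after the result was seen, while the counts over other splits, the search for libraries far from their diet and the cholesterol interaction were planned.

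In HS_Chol 134 of the 216 genes higher than in NC (62.0%) overlap a gene on the opposite strand or match no annotated gene, against 18.5% of the genes tested. Gm10680, opposite Apoa4 and named after its values were seen, stood at 20.3 CPM in HS_Chol and 0.456 CPM in NC, while Apoa4 stood at 328 and 181 CPM. A response to cholesterol shared by both backgrounds would have raised these genes in Chol_CA against CA as well. Their median log2 fold change there was −0.11 (quartiles −0.83 and 0.44). Of the 134, 6.72% were called higher there, as were 8.91% of all tested genes of this class (a test against all genes, run first, was dropped). These values were not used to choose the genes, and they show no rise of the set. In HS_Chol against HS the median was 4.08 (2.32 and 5.11). The genes were chosen as higher in the same HS_Chol libraries, so that median was bound to be high and gives no separate evidence. Weaker strand selection in the HS_Chol libraries is a candidate explanation, since light-strand tRNA reads per 1000000 heavy-strand mRNA reads were at least 673 in each of them and at most 83.4 in the 17 others. The labels give no preparation date and all 3 HS_Chol libraries show the rise, so a response of single genes to this diet alone stays open and untested.

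The sign of the trend with transcript length parts the libraries of 4 diets, 7 negative against 13 positive, and 5969 genes (47.4% of those tested) differed between the sets with diet in the fit, such as Bmpr2 at −2.51 ± 0.17 and Lyz1 at 3.28 ± 0.42 on the log2 scale (negative against positive; genes chosen after their values were seen). Transcript length and GC content alone do not account for it: with an offset for both, 4113 genes still differed. The rank correlation of the difference with length over genes went from −0.566 to 0.013. The sets were defined by the length trend and the offset was fitted to remove it, so both correlations follow from the construction. The uneven spread of the sets over diets does not make most of the diet calls, since with the set as a term 68.8% of the calls of the cholesterol interaction were found again, and between 89.4% (HS_Chol against HS) and 99.7% (HS_Chol against NC) of those of the other comparisons. A difference in RNA quality or library batch may be the source, but the labels record neither, so this was not tested. No biological explanation was tested, since the design gives no group that follows the sets.

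In CA 18 of 25 male-biased genes fell and 11 of 14 female-biased genes rose. Female animals in the group are excluded by Xist, at most 0.12 CPM in a CA library, beside 4 Y-linked genes at 11.9 CPM or more. The length-trend sets are excluded for the fall of male-biased genes: of the 18, 18 were called lower again among libraries with a positive trend. The rise of female-biased genes was not part of that test. Over the 10 outside the drug-receptor list, mean log2 CPM was 3.85 to 4.53 in the CA libraries with a positive trend and 1.53 to 1.87 in those of NC. CA_0 and NC_3, which have a negative trend, stood at 1.94 and 1.95. Drug-receptor targets as the only cause stay open: 7 of 10 female-biased genes outside that list rose and 1 fell, but their mean log2 CPM did not pass (difference 1.79, exact permutation p = 0.0571, 4 of 70 label assignments; CA_0 at 1.94 and NC_3 at 1.95), and the list removes 0 of the 25 male-biased genes, so their fall (difference −2.96, exact permutation p = 0.0286, 2 of 70; camera p = 0.00239 with an estimated correlation, and 0.0441 for the 10 female-biased genes) restates the pattern, as do tests of both sets joined that were run first. Lower growth hormone, IGF and insulin signalling could take part but was not decided: 1 of its 19 genes rose and 3 fell, 1 and 6 adjusted over the list alone (camera adjusted p = 0.0374; adjusted p = 0.327 with an estimated correlation). Cux2, a female-biased regulator gene chosen after its values were seen, stood at 0.47 (CA_0), 8.83, 43.6 and 22.3 CPM in CA and at 1.06 CPM or less in the other libraries.

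Chance was tested by counting the splits of the same libraries that called as many genes, the real split included. The share of such splits, not adjusted over the comparisons, was under 0.05 for HS_Chol against NC (1 of 35 splits, 287 genes, highest other 155), Chol_CA against NC (1 of 35, 3063, highest other 2105) and CA against NC (1 of 35, 1238, highest other 4). It was also under 0.05 for HS_Chol against HS (1 of 56, 283, highest other 18) and Chol_CA against CA (1 of 35, 2676, highest other 1646). A share of 1 of 35 is the lowest that 35 splits can give. For HS against NC the share was under 0.05 too (3 of 100 splits drawn from 126, 82 genes), but other splits called 306 and 2956 genes. Chance is not excluded there, since the libraries differ in more than diet. For the cholesterol interaction the count (4 of 100 splits drawn from 3920; 756, highest other 1118) decides nothing, since most of these splits mix Chol_CA with CA and so remove that contrast. Of the 3 other splits that kept Chol_CA apart from CA, 2 called more genes than the real one (873, and 998 with Chol_CA and CA exchanged). The split with 2956 genes parts NC_3, HS_0, HS_1 and HS_2 from the other HS and NC libraries, exactly as the length trend does, and points to that structure of the samples. The splits with 2105 and 1646 genes each exchange 1 library of negative trend for 1 of positive trend (NC_3 for Chol_CA_3, and CA_0 for Chol_CA_3). Within the libraries with a positive trend HS against NC gave 148 higher and 183 lower genes.

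Of 28 groups of library measures 5 had 1 library far from the others of its diet, and of 195 groups of named genes 9 did, where chance gives about 5% of groups. NC_3 held 13.7% mitochondrial reads, 26.9% of reads in the 10 genes highest on average over all libraries, a slope with length of −0.236 and antisense reads at 0.448% of their partners' reads, and CA_0 held such antisense reads at 0.461%. Among genes, NC_3 stood apart for Acss2 (516 CPM), Chrna4 (59.7 CPM) and Col6a3 (12.8 CPM), HS_0 for Cd74 (114 CPM), HS_3 for Cyp7a1 (37.0 CPM) and HS_2 for Pnpla3 (48.9 CPM). Chol_CA_3 stood apart for Glul (824 CPM), NC_0 for Mup11 (495 CPM) and Chol_CA_1 for Mup11 (176 CPM).

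By a test of the difference itself, the change with cholesterol differed between the sucrose and the cholic acid background for 11 named genes. Cyp4a14, Acot3, Cyp4a10, H2-M2, Tff3 and Mup11 were named as the largest differences called in this same test. That they pass gives no separate evidence. The HS_Chol and HS libraries also differed in light-strand reads and length trend, so these differences are not isolated to the sterol. Cyp7a1, Cyp8b1 and Sqle already stood far lower in CA than in HS, so their differences also depend on unlike starting levels. The log2 differences, sucrose minus cholic acid, were 12.32 for Cyp4a14, 8.02 for Acot3, 8.01 for Cyp4a10, −6.28 for Tff3, −6.04 for Mup11, −3.62 for Cyp7a1, −3.57 for Trem2, −2.58 for Sqle, −2.15 for Cyp8b1 and 1.03 for Abcg5. For H2-M2, with 1 read in CA, it was −7.39 (adjusted p = 0.0428), a fitted value that is no bound. That call was lost without HS_0, HS_1, HS_4, CA_1, CA_2, CA_3, HS_Chol_1, HS_Chol_2, Chol_CA_0 or Chol_CA_1 (adjusted p 0.0542 to 0.11), in a fit of the groups compared (0.0572) and among libraries with a positive length trend (0.125).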

How the results depend on the processing

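The alternatives on strand overlap, length trend and length with GC content were chosen after seeing the data, and the others were planned. No call of a named gene reversed in any alternative run. With median-ratio size factors, the stricter filter, or mitochondrial, rRNA and small RNA genes left out, every count of called genes stayed within 1.5 times the reported one. Of the calls of named genes, 14 of 118 were lost with the libraries of negative length trend left out, 7 of 114 in a fit of the groups compared, 6 of 120 without a filter, 3 of 99 with opposite-strand genes left out, 3 of 120 with the length and GC offset, 1 of 119 with the stricter filter and none with DESeq2. Leaving out 1 library in turn ended such a call in 84 of 993 tests. No paired analysis was possible because the columns of the table carry no replicate number of the labels. Fits planned with a replicate block, with the HS sample of conflicting labels counted as HS or as NC, and all fits of the sixth-diet comparisons and of the sucrose and cholic acid interactions were not run. A level of 3 reads over a group corresponds to 0.0821 (CA) to 0.158 CPM (HS_Chol), and lower levels were taken as not detectable.

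Other counts moved by more than 1.5 times. Where fewer libraries or genes entered and a count fell, the fall is part of the construction. Fewer libraries do not by themselves explain counts that rose, as most did among the libraries of positive trend. The cause of those rises and of the other moves was not tested. DESeq2 called 59 higher and 139 lower in HS against NC, 399 and 150 in HS_Chol against NC, and 336 and 157 in HS_Chol against HS. The term for the length-trend sign gave 50 and 100, 451 and 198, and 358 and 136 in the same order, 1036 and 968 in CA against NC, and 1529 lower in Chol_CA against CA. The libraries of positive trend alone gave 148 and 183 in HS against NC, 796 and 620 in HS_Chol against NC, 1423 and 1385 in CA against NC, 180 lower in HS_Chol against HS, 1681 lower in Chol_CA against CA, and 969 and 641 in the interaction. The length and GC offset gave 42 and 108 in HS against NC, 110 lower in HS_Chol against NC and 1511 lower in Chol_CA against CA. A minimum change of 2-fold left 35 lower in HS against NC, 47 in HS_Chol against NC, 360 in Chol_CA against NC, 315 in CA against NC, 49 in HS_Chol against HS and 327 in Chol_CA against CA. Without a filter 358 were higher in HS_Chol against NC and 346 in HS_Chol against HS. Without opposite-strand genes 48 and 41 were called in HS_Chol against NC and 45 and 45 in HS_Chol against HS. A fit of the groups compared gave 701 lower in Chol_CA against NC, and 1063 higher and 523 lower in Chol_CA against CA.

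Leaving out 1 library gave 6 to 58 higher and 29 to 100 lower genes in HS against NC (higher: 12 without NC_0, 12 without NC_1, 6 without NC_2, 58 without NC_3, 17 without HS_0, 13 without HS_1, 17 without HS_2, 10 without HS_3, 13 without HS_4; lower: 29 without NC_2, 100 without NC_3, 35 without HS_1, 34 without HS_3, 31 without HS_4). It gave 36 (without HS_Chol_0) to 82 lower in HS_Chol against NC and 376 (without NC_0) to 685 higher in CA against NC, with 422 without NC_2 and 423 without CA_3. It gave 33 (without HS_Chol_0) to 80 lower in HS_Chol against HS, with 53 without HS_1, 38 without HS_Chol_1 and 49 without HS_Chol_2. In Chol_CA against CA it gave 960 (without CA_2) to 1939 higher, with 1095 without CA_3. In the interaction it gave 318 to 707 (without CA_0) positive and 130 (without CA_2) to 608 (without CA_0) negative, with 156 without CA_3, 191 without HS_Chol_0, 136 without HS_Chol_1, 204 without HS_Chol_2 and 187 without Chol_CA_0.

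Over lists with at least 2 measured genes, 8 passed upward and 11 downward in HS against NC at the preset correlation and 0 and 0 by camera with an estimated correlation, where 2 and 4 had an unadjusted p under 0.05. The counts were 9 and 11 against 1 and 2 in HS_Chol against NC, 14 and 16 against 2 and 5 in Chol_CA against NC, 15 and 17 against 1 and 4 in CA against NC, 7 and 7 against 1 and 1 in HS_Chol against HS, 14 and 12 against 1 and 3 in Chol_CA against CA, and 7 and 13 against 2 and 0 in the interaction. With the length-trend term 5 passed upward in HS against NC, 12 upward in HS_Chol against HS and 7 downward in the interaction, and with the libraries of positive trend 3 downward in HS_Chol against HS.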

Other observations

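Tests between and within the length-trend sets were chosen after seeing the data, and the list tests were planned. In Chol_CA against NC, further lists moved that the report does not describe. Of 14 T and NK cell markers 13 rose, the same adjusted over the list alone (camera adjusted p = 3.85e-06, adjusted p = 0.226 with an estimated correlation). With diet in the fit 12 of the 14 were also higher in the libraries with a negative length trend (camera adjusted p = 0.00479, adjusted p = 0.903 with an estimated correlation), and among libraries with a positive trend 11 of 11 tested rose in Chol_CA. Of 15 dendritic cell and MHC class II genes 14 rose, the same adjusted over the list alone (camera adjusted p = 4.20e-11, adjusted p = 0.0794 with an estimated correlation). With diet in the fit 8 of the 15 were higher and 0 lower in the libraries with a negative length trend (camera adjusted p = 0.0546, adjusted p = 0.903 with an estimated correlation). Of 26 acute phase genes 15 rose, or 18 adjusted over the list alone (camera adjusted p = 3.33e-06, adjusted p = 0.146 with an estimated correlation). Saa1, an acute phase apolipoprotein gene that shares reads with Saa2, and Lcn2, a siderophore-binding protein gene, were chosen after their values were seen. Saa1 stood at 903 and 2200 CPM in Chol_CA_0 and Chol_CA_1, the libraries with a negative length trend, and at 380 and 254 CPM in the others, against 28.2 ± 15.4 CPM (SD, n = 4) in NC. Lcn2 stood at 498, 918, 113 and 39.2 CPM in the same order, against 3.07 ± 1.11 CPM in NC. Of 30 lysosomal genes 15 rose and 2 fell, or 16 and 2 adjusted over the list alone (camera adjusted p = 3.90e-07, adjusted p = 0.105 with an estimated correlation). Of 31 cell cycle genes 16 rose, or 25 adjusted over the list alone (camera adjusted p = 3.67e-06, adjusted p = 0.305 with an estimated correlation), and 2 rose among libraries with a positive length trend. Of 26 interferon-stimulated genes 17 rose, or 21 adjusted over the list alone (camera adjusted p = 8.60e-08, adjusted p = 0.275 with an estimated correlation), and 6 rose among libraries with a positive length trend.

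Of 34 nuclear genes of oxidative phosphorylation 15 fell, or 16 adjusted over the list alone (camera adjusted p = 2.91e-06, adjusted p = 0.329 with an estimated correlation). This list also differed between the length-trend sets, with 26 of 34 higher and 1 lower in the negative set (camera adjusted p = 4.56e-08, adjusted p = 0.903 with an estimated correlation), and among libraries with a positive trend 27 fell in Chol_CA. Of 24 genes of methionine, one-carbon and choline metabolism 13 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 4.51e-06, adjusted p = 0.0308 with an estimated correlation). Of 18 pericentral genes 14 fell, the same adjusted over the list alone (camera adjusted p = 7.02e-09, adjusted p = 0.00692 with an estimated correlation). In CA 13 of 23 NRF2 and glutathione genes rose, or 14 adjusted over the list alone, where 2 fell (camera adjusted p = 3.80e-09, adjusted p = 0.162 with an estimated correlation).

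By edgeR, no sinusoidal endothelial marker of 18 was called in HS, HS_Chol or CA against NC, over all genes or adjusted over the list alone (camera adjusted p = 0.000181, 0.000866 and 0.0186, upward; adjusted p = 0.602, 0.576 and 0.534 with an estimated correlation). Among libraries with a positive length trend 14, 14 and 17 were higher in these diets, and 18 in Chol_CA, each against the same 3 NC libraries. The blood cell list of 7 genes and the cholangiocyte list of 15 held 2 and 4 called genes at most against NC: 2 blood genes fell in CA, the same adjusted over the list alone (camera adjusted p = 0.0568), and 4 cholangiocyte genes rose in Chol_CA, the same adjusted over the list alone (camera adjusted p = 0.121). With diet in the fit 5 of the 7 blood genes were higher in the libraries with a negative length trend (camera adjusted p = 0.0181, adjusted p = 0.903 with an estimated correlation).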
